A study of Homo sapiens with 4 samples.

How the data were processed

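Total RNA from primary human keratinocytes was measured on 4 Affymetrix HG-U133 Plus 2.0 arrays, which carry oligonucleotide probe sets placed mostly near the 3' end of each transcript. Per the labels, 2 arrays came from cells given a control siRNA and 2 from cells given an siRNA against ANCR, each at 1 nmol. Cells were kept below confluence in Gibco SFM, RNA was extracted with Qiagen RNeasy kits, and biotin-labelled RNA was made with the Affymetrix 3' IVT Express kit, per the labels' protocols. Such labelling starts from the poly(A) tail. The design text calls the arrays of a group biological duplicates. It does not say whether they came from separate donors, so p-values measure only the spread between these samples.

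The deposited values are log2 expression values made by the authors with RMA in R 2.11.1, per the submitters' processing notes. RMA corrects the background, sets the arrays to one common distribution and summarises the probes of each probe set. The probe set definition and the annotation version are not given in the sources used here. The values ran from about 2.3 to 14.8 on each array, with medians of 5.65 and 5.67 on the control arrays and 5.68 and 5.67 on the arrays labelled ANCR siRNA. No centring by gene was seen. Equal distributions were imposed by RMA, so a change shared by most transcripts would not appear. RMA values carry no detection call, and dim probe sets are compressed toward the background, so folds from a dim level, such as those of ZNF750, S100A12 and DSC1, can understate the change. The number of arrays limits the precision.

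The table held 54675 probe sets, of which 62 were controls and 54613 were tested. Gene names came from the platform annotation: 41091 of the tested probe sets named 1 gene, 1801 named several and 11721 had no name here. Of those with 1 gene, 41037 were matched by Entrez identifier to the RefSeq gene table of GRCh38.p14. That table served only for current symbols, chromosomes and the order of neighbouring genes. No gene was named from a probe set with several genes. Each of the 19777 genes was represented by its probe set with the highest mean over the 4 arrays. Affymetrix probe sets with names ending in _s_at or _x_at can hybridise with transcripts of related genes, so values within the SPRR, KRT and SERPINB families are less certain.

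Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariate). Adjusted p-values are Benjamini-Hochberg values over the 54613 probe sets, with a threshold of 0.05. Differences are the mean of the arrays labelled ANCR siRNA minus the mean of the control arrays. Errors are the SD of 2 arrays or the SE from limma. The fit was tested on simulated data with the same number of probe sets and arrays and a like spread. It recovered 73 of 100 probe sets changed by 2-fold and 100 of 100 changed by 4-fold, and 8 of its 181 calls were false. Simulated noise was independent between probe sets, and all changed ones lay above the median level. False calls from differences shared by many probe sets were therefore not tested.

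A total of 16 gene lists were tested with camera from limma, which asks whether a list ranks above or below the other genes, at a preset correlation of 0.01. Members with no probe set named for them alone were not analysed here. Each list was also tested with a correlation estimated from the residuals and with fry, which tests whether the members move one way on balance. With an estimated correlation, camera takes its p from the residual degrees of freedom, which are few with 4 arrays. A call lost there therefore does not by itself show that members are correlated. For skin barrier lipids the estimated correlation was -0.0070, below the preset 0.01, yet the unadjusted camera p went from 2.22e-11 to 0.0174. Several other lists had estimates above the preset. They were 0.21 for epidermal differentiation, 0.33 for differentiation factors, 0.18 for inflammatory genes, 0.29 for melanocyte markers and 0.10 for G2 and mitosis. For these lists correlation and few degrees of freedom can both cost a call, and p-values at the preset can be too small. SESN2 and SPATA18 each stood in 2 lists, and the others in 1. The named genes are the targeted RNA, the 12 largest rises and 12 largest falls among genes past the adjusted threshold whose arrays did not overlap between groups, and up to 4 members of each list with the smallest p. Uncharacterised loci were passed over. Genes named outside this rule were chosen after their values were seen, as is said where they appear.

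The groups, the tests, the lists, the rule for named genes and all but 1 of the alternatives were fixed before the data were examined. The alternatives were the replicate number as a block, cyclic loess between arrays, dim probe sets left out, an intensity trend in eBayes, each array left out, an adjusted threshold of 0.10, the mean of a gene's probe sets, a 2-fold difference with separated groups, an estimated correlation and fry. The exception, a count of genes with 2 bright probe sets that agree, was chosen after seeing the data. A fit without 1 array leaves a group with a single array and fewer degrees of freedom. A call lost there can be a loss of power and need not mean that the result rests on that array. Gene families, runs of neighbouring genes and 2 further gene lists were also examined after seeing the data, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Plots were drawn with matplotlib 3.10.9. Control probe sets stayed out of the tests and served as a measure of signal along the actin and GAPDH transcripts.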

Results

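Keratinocytes are the main cells of the epidermis: progenitors in the basal layer divide, then leave it and build the cornified barrier. ANCR, now named DANCR, is a long non-coding RNA. The comparison of 2 arrays labelled ANCR siRNA with 2 control siRNA arrays asked which transcripts depend on this RNA in keratinocytes grown as progenitors. The arrays of one group correlated at 0.997 (control) and 0.996 (ANCR siRNA) across probe sets, and arrays of different groups at 0.991 to 0.992. Probe sets are not independent replicates. The SD of the difference between replicates was 0.20 on the log2 scale in either group.

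The targeted RNA was not lower on the arrays labelled ANCR siRNA. Its single probe set (DANCR, Entrez gene 57291, chromosome 4) read 10.64 and 10.69 on the control arrays and 10.92 and 10.93 on the others. The log2 difference was 0.26 (SE 0.10, 95% interval 0.02 to 0.49), a 1.19-fold higher mean with an adjusted p of 0.278. This goes against the label, so the arrays are called by their label throughout. Which part of the RNA this probe set and the siRNA match was not analysed here. Every direction given for this comparison therefore rests on the labels and not on a measured loss of the target.

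Many transcripts of the epidermal differentiation list, alarmins among them, were far higher on the arrays labelled ANCR siRNA. The calcium-binding alarmin S100A7 rose 65.1-fold, from 6.05 ± 0.54 to 12.07 ± 0.15 (SD, n = 2 per group). The related S100A9, S100A12 and S100A8 rose 43.8-fold, 38.2-fold and 24.6-fold. S100A8 read 14.45 on both arrays labelled ANCR siRNA, near their highest values of 14.73 and 14.76, where probe signal can saturate, so the folds of S100A8 and S100A9 (14.07) give no order. The cornified envelope precursor IVL (involucrin) rose 19.98-fold, from 8.08 ± 0.17 to 12.40 ± 0.04, and KRT1, the first keratin of suprabasal epidermis, rose 19.8-fold, from 5.37 ± 0.06 to 9.68 ± 0.24. KRT4, a keratin typical of internal stratified epithelia, rose 44.7-fold.

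Also among the 12 largest rises were IGFL1, a secreted member of the IGF-like family (51.4-fold), SBSN (24.9-fold), the protease inhibitors SERPINB3 (21.3-fold) and PI3 (20.04-fold), and KRTDAP (20.8-fold). The SEs of these 12 log2 changes lay far below the changes, with 0.23 for S100A7 and 0.12 for IVL, and each had an adjusted p from limma of 1.38e-04 or less. Both arrays labelled ANCR siRNA lay above both control arrays for every one of these genes, as the rule that named them asks. Without ANCR siRNA replicate 2, PI3 no longer passed (adjusted p 0.0558). These rises were seen on arrays whose actin control showed a 3' minus 5' difference 1.79 larger, in log2, than on the control arrays.

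**Figure D1:**
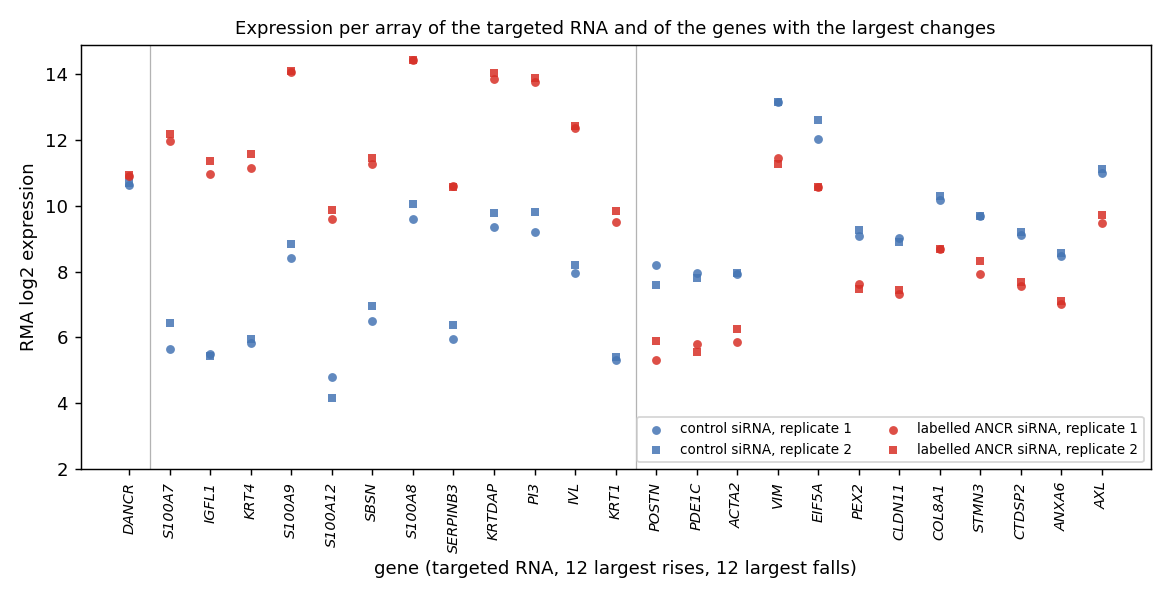
RMA log2 expression on each of the 4 arrays (y axis) of the targeted RNA, the 12 genes with the largest rises and the 12 with the largest falls (x axis). Each point is 1 array, blue for control siRNA and red for the arrays labelled ANCR siRNA. S100A7 lies at 6.05 on average on the control arrays and at 12.07 on the others, while DANCR lies at 10.67 and 10.92.

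More genes rose than fell by at least 2-fold. Of 19777 genes, 432 were higher and 160 lower at the adjusted threshold, and with a change of at least 2-fold 241 were higher and 28 lower. The replicate block, which leaves fewer residual degrees of freedom, gave 128 higher and 9 lower by at least 2-fold. At least 8-fold rises were found for 40 genes. By probe set, 711 of 54613 were higher and 537 lower, 346 and 117 of them by at least 2-fold, and 8422 had an unadjusted p under 0.05. With dim probe sets left out, 912 probe sets were higher and 925 lower with no fold threshold, while 210 genes were higher and 28 lower by at least 2-fold. Fewer of the 269 genes past 2-fold passed with any 1 array left out. Such a fit leaves a group with a single array, so a lost call can reflect less power.

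The largest falls were smaller than the largest rises. POSTN, the matrix protein periostin, fell 4.94-fold, from 7.90 ± 0.41 to 5.59 ± 0.41 (SD, n = 2 per group). ACTA2, smooth muscle actin, fell 3.67-fold, and VIM, the intermediate filament protein vimentin, fell 3.43-fold, from 13.14 on either control array to 11.46 and 11.27. The phosphodiesterase PDE1C fell 4.58-fold, the receptor tyrosine kinase AXL 2.76-fold, the tight junction protein CLDN11 2.99-fold and the collagen COL8A1 2.95-fold.

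The other genes among the 12 largest falls were EIF5A (3.32-fold), PEX2 (3.11-fold), STMN3 (2.93-fold), CTDSP2 (2.89-fold) and ANXA6 (2.77-fold). Adjusted p-values of the 12 ran from 3.26e-04 for PDE1C to 0.0065 for POSTN and EIF5A. With the replicate block only 9 genes in all were lower by at least 2-fold, so not all of the 12 passed in that fit. Only for CTDSP2 and AXL did every probe set of the gene pass as lower; for ACTA2, EIF5A, PEX2, CLDN11 and COL8A1, 1 of 3 did. When the probe sets of a gene were averaged, 10 genes were lower by at least 2-fold, against 28. Without ANCR siRNA replicate 2, only PDE1C and ACTA2 of the 12 passed, with adjusted p-values of the others up to 0.249 (EIF5A), and without replicate 1 these and VIM passed, with others up to 0.190. POSTN also missed without control replicate 1 (0.0609), and STMN3 without either control array (0.0600 and 0.0713). The same larger 3' minus 5' difference accompanied these falls.

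The list of epidermal differentiation and cornified envelope genes rose: 40 of 55 measured members were higher and none lower, and 49 were higher when adjusted over the list alone. At an unadjusted p under 0.05, 49 were higher and none lower with limma. Its median log2 change was 1.61 (camera adjusted p = 7.28e-61). The adjusted p was 0.219 with the estimated correlation of 0.21, a test that few lists could pass with 4 arrays, and 0.0193 with fry. DSC1, a desmosomal cadherin, rose 14.97-fold, TGM1, the enzyme that cross-links the envelope, 5.99-fold, and FLG (filaggrin) 4.48-fold. LORICRIN rose 2.67-fold from 5.66 ± 0.03 to 7.08 ± 0.26. KRT10, the usual partner of KRT1, was bright in both groups, with a log2 difference of 0.31 and an adjusted p of 0.204. KRT2, CASP14, TGM3 and RPTN did not pass, with log2 differences of 0.37, 0.42, -0.11 and 0.09. All of these read below the median probe set, where changes can be understated. They and TGM1, FLG, LORICRIN and KRT10 were chosen after their values were seen.

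Genes of skin barrier lipids shifted the same way, with 8 of 26 members higher and none lower, and 13 higher and 1 lower when adjusted over the list alone. The median log2 change was 0.41 (camera adjusted p = 1.18e-10), and the adjusted p was 0.219 with an estimated correlation. The lipid transporter ABCA12 rose 5.47-fold (log2 2.45, SE 0.18), the cholesterol sulfotransferase SULT2B1 5.78-fold, the lipoxygenase ALOX12B 3.55-fold and GDPD3 4.84-fold. With limma, 14 members were higher and 1 lower at an unadjusted p under 0.05. ABCA12 missed the threshold without ANCR siRNA replicate 1 (adjusted p 0.0795) or 2 (0.0702), and ALOX12B without either control array (0.0506 and 0.0595) or ANCR siRNA replicate 2 (0.0627).

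Transcription factors of epidermal differentiation followed, with 13 of 33 members higher and none lower, and 16 higher and 2 lower when adjusted over the list alone. Their median log2 change was 0.41 (camera adjusted p = 2.12e-14), and the adjusted p was 0.359 with an estimated correlation. ZNF750, an activator of the terminal programme, rose 13.2-fold, from 3.34 and 3.20 on the control arrays to 6.98 and 7.01 on the others. Its control level lay far below the median probe set, with no detection call, so this fold can understate the change. The grainyhead factors GRHL1 and GRHL3 rose 11.4-fold and 6.27-fold, and HOPX rose 5.06-fold. As probe sets, 1 of 2 of GRHL1, 1 of 3 of HOPX and the 1 of GRHL3 passed as higher. Counting members with an unadjusted p under 0.05, 19 were higher and 2 lower. All 3 of these lists rose on arrays with the larger actin 3' minus 5' difference of 1.79.

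Basal progenitor and hemidesmosome genes did not shift as a list: 3 of 34 rose and none fell, with 3 higher and 2 lower when adjusted over the list alone. The 3 were BCAM, a laminin receptor (2.40-fold), and ID1 (1.84-fold) and ID3 (1.61-fold), inhibitors of differentiation factors. All 3 missed the threshold without either array labelled ANCR siRNA (adjusted p 0.171 to 0.368) or without control replicate 1 (0.0789 to 0.238), as did ID1 and ID3 without control replicate 2 (0.0807 and 0.160). In the whole list, 7 were higher and 7 lower at an unadjusted p under 0.05. The basal keratins KRT5 and KRT14 had log2 differences of -0.0015 (95% interval -0.24 to 0.24) and 0.02 (-0.21 to 0.26), and were added after their values were seen. Both lay near the highest values of the arrays, where probe signal can saturate, so a change in either can be hidden. KRT15 differed by -0.51, with an adjusted p of 0.0637. The list's median was -0.11 and its mean 0.0041, and camera pointed down with an adjusted p of 0.475, against 0.831 with an estimated correlation.

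Genes of the cell cycle were slightly lower as lists, with no single member past the adjusted threshold. Of 32 S phase genes, 1 was higher and 6 lower at an unadjusted p under 0.05 with limma, and 1 higher (CCNE1, log2 0.50) and 1 lower (RRM2, -0.50) when adjusted over the list alone. Their median was -0.19 (camera adjusted p = 0.0010), with an adjusted p of 0.350 with an estimated correlation. Of 46 G2 and mitosis genes, 1 was higher and 5 lower at an unadjusted p under 0.05, and none was past the threshold adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.0228), with an adjusted p of 0.529 with an estimated correlation, and cyclic loess gave 0.113. That call was lost without control replicate 1 (0.468) or ANCR siRNA replicate 2 (0.406). The lower members included CENPA (-0.60, adjusted p 0.0559), and these small differences stood on arrays with the larger 3' minus 5' difference.

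Inflammatory and NF-kB response genes rose in part: 13 of 35 members were higher and none lower, and 16 were higher and 2 lower when adjusted over the list alone. The counts at an unadjusted p under 0.05 were 16 higher and 4 lower. The median was 0.16 (camera adjusted p = 1.11e-07), with an adjusted p of 0.359 with an estimated correlation. IL36RN, an antagonist of interleukin-36 signalling, rose 6.51-fold and the interleukin IL36G 4.53-fold. The gelatinase MMP9 rose 6.19-fold, from 9.06 ± 0.09 to 11.69 ± 0.30 (SD, n = 2 per group), and the iron-chelating protein LCN2 rose 4.25-fold (adjusted p 0.0555 without ANCR siRNA replicate 2), again with the 1.79 larger actin 3' minus 5' difference.

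Interferon response genes did not shift as a list. None of the 43 passed with limma, 9 were higher and 5 lower at an unadjusted p under 0.05, and 3 were higher and 1 lower when adjusted over the list alone. BST2 differed by 0.56 (adjusted p 0.0502) and GBP1 by 0.77 (0.0534). The median was -3.9e-04 and the mean 0.07, with camera up (adjusted p = 0.779, and 0.916 with an estimated correlation). Without control replicate 2 it pointed down (0.378).

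Of 27 p53 targets only TP53I3 rose (1.79-fold) and none fell, and TP53I3 missed the threshold when any of the 4 arrays was left out (adjusted p 0.0988 to 0.270). At an unadjusted p under 0.05, 3 were higher and 3 lower, and 2 were higher and 1 lower when adjusted over the list alone. The median was -0.0044, the mean 0.03 and camera pointed up (adjusted p = 0.815, and 0.912 with an estimated correlation). It pointed down without ANCR siRNA replicate 2 (0.913) or with the mean of a gene's probe sets (0.930). CDKN1A, the cell cycle inhibitor p21 and a member of this list added after its value was seen, differed by 0.01 (95% interval -0.33 to 0.35).

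The unfolded protein and amino acid stress list and the sterol biosynthesis list were both slightly lower. Of 32 stress genes, PDIA4, a protein disulfide isomerase, fell 1.72-fold and none rose, with 0 higher and 1 lower when adjusted over the list alone. Among all 32, 10 were lower and none higher at an unadjusted p under 0.05, the median was -0.09 (camera adjusted p = 0.0030), and the adjusted p was 0.372 with an estimated correlation and 0.195 with fry. Of 24 sterol genes, LSS, the lanosterol synthase, fell 1.61-fold and none rose, with 4 lower and none higher when adjusted over the list alone. Among all 24, 6 were lower and none higher at an unadjusted p under 0.05, the median was -0.14 (camera adjusted p = 0.0014), and the adjusted p was 0.329 with an estimated correlation and 0.0388 with fry. The probe sets of LSS differed, with 1 of 3 past the threshold, and their mean gave -0.30, which did not pass. INSIG1 did not pass by its brightest probe set (log2 -0.48, limma adjusted p 0.113), but 2 of its 3 probe sets passed as lower. PDIA4 and LSS also missed the threshold when any of the 4 arrays was left out (adjusted p 0.123 to 0.248). Both lists were lower on the arrays with the larger 3' minus 5' difference.

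None of the 21 polycomb repressive complex genes passed with limma, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 1 was higher and 2 lower. EZH2, the histone methyltransferase of the complex, read 8.81 ± 0.05 on the control arrays and 8.89 ± 0.01 on the others (SD, n = 2 per group). It was added after its values were seen. The list's median was 0.01, its mean -0.04 and camera pointed down (adjusted p = 0.475, and 0.663 with an estimated correlation). Of the 9 genes in the list of the targeted RNA and its neighbours on chromosome 4, none passed, 1 was higher and 2 lower at an unadjusted p under 0.05, and only SGCB (-0.44) was lower when adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.130, and 0.423 with an estimated correlation). Without control replicate 2 that test passed (0.0308).

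**Figure D2:**
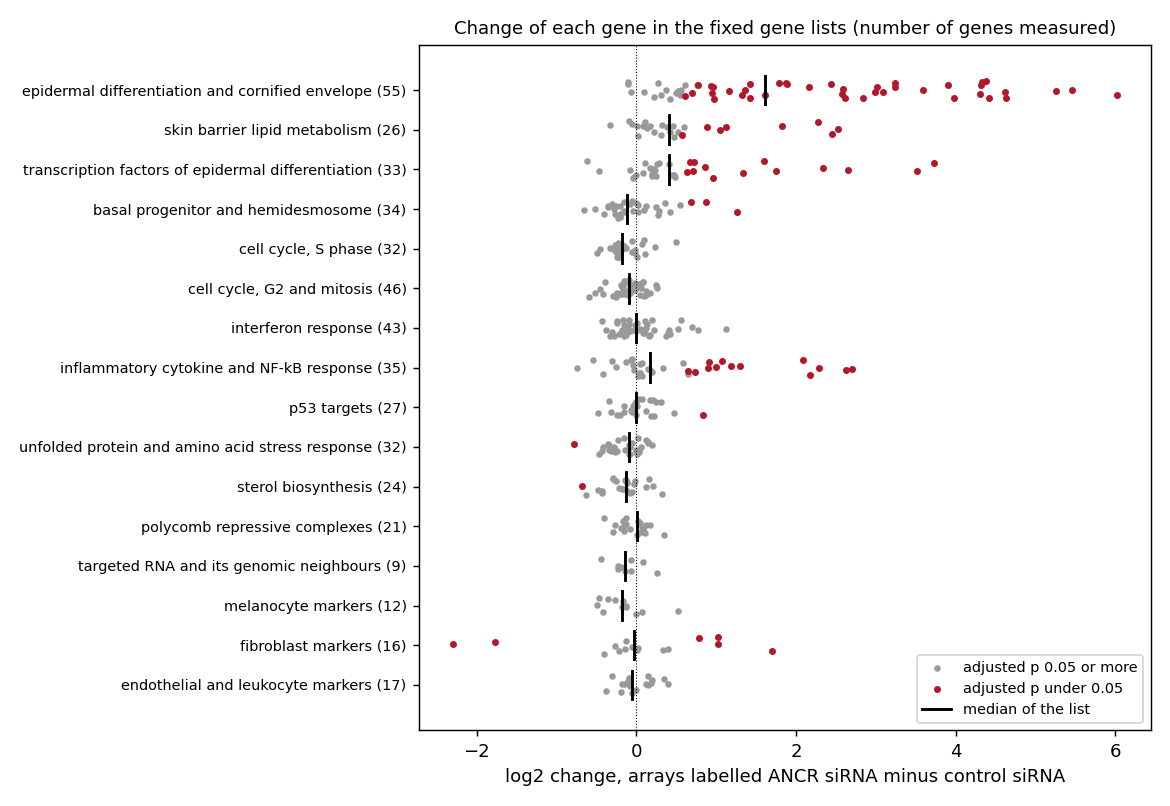
Log2 change of each measured gene (x axis, arrays labelled ANCR siRNA minus control siRNA) in the 16 gene lists (y axis, number of genes in brackets). Each point is 1 gene, red where the adjusted p was under 0.05 and grey otherwise, and black bars are list medians. The epidermal differentiation list has the highest median, 1.61, and the other medians lie between -0.19 and 0.41.

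Markers of other cell types gave a mixed picture. The melanocyte marker TYRP1 was bright in both groups, at 11.85 ± 0.07 and 11.68 ± 0.01 (SD, n = 2 per group), and was added after its values were seen. None of 12 melanocyte markers passed with limma, 1 was higher and 3 lower at an unadjusted p under 0.05, and 1 was higher and 1 lower when adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.0244, and 0.529 with an estimated correlation). That call was also lost without control replicate 2 (0.112), without ANCR siRNA replicate 1 (0.252), with dim probe sets left out (0.0653), with the mean of a gene's probe sets (0.193) and with fry (0.442).

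Of 16 fibroblast markers, S100A4 (3.24-fold), THY1 (2.03-fold), COL5A1 (2.03-fold) and FAP (1.72-fold) rose, while POSTN and VIM fell. COL5A1 and FAP were added after their values were seen. THY1 missed the threshold when any of the 4 arrays was left out (adjusted p 0.0558 to 0.208), and S100A4 without either array labelled ANCR siRNA (0.0613 and 0.107). Adjusted over the list alone, 6 were higher and 3 lower. The median was -0.03, the mean -7.8e-04 and camera pointed up (adjusted p = 0.679, and 0.831 with an estimated correlation). None of 17 endothelial and leukocyte markers passed with limma, over all genes or adjusted over the list alone, and 2 were higher and 2 lower at an unadjusted p under 0.05. Their median was -0.05 (camera adjusted p = 0.912, and 0.916 with an estimated correlation), and the direction turned up with fry (0.914) and with the mean of a gene's probe sets (0.930).

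Signal along the actin and GAPDH control transcripts differed between the groups. The actin 3' probe set exceeded the 5' one by 3.82 ± 0.42 on the control arrays and 5.61 ± 0.20 on the arrays labelled ANCR siRNA (log2, SD, n = 2 per group). For GAPDH the difference was 0.78 ± 0.29 and 1.84 ± 0.13. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so these differences are given as values.

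**Figure D3:**
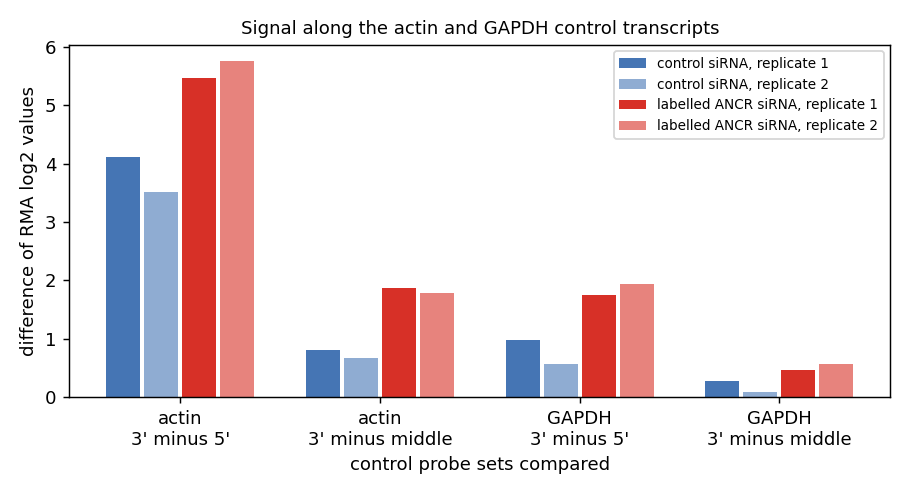
Difference of RMA log2 values between control probe sets at the 3' end and at the 5' end or the middle of actin and GAPDH (y axis) for each of the 4 arrays. Each bar is 1 array, blue for control siRNA and red for the arrays labelled ANCR siRNA. Actin 3' minus 5' averages 3.82 on the control arrays and 5.61 on the others.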

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

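The tests of the genes past 2-fold and of the targeted RNA in this part were chosen only after the result was seen. The test of probe sets that lag behind a gene's brightest one was chosen before.

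Probe sets that no comparison of genes used showed a difference between the groups. The arrays labelled ANCR siRNA exceeded the control arrays by 1.79 for actin 3' minus 5', 1.09 for actin 3' minus middle, 1.06 for GAPDH 3' minus 5' and 0.34 for GAPDH 3' minus middle, all in log2. In each of these measures both arrays of that group lay above both control arrays. The mean of the 18 hybridization spikes was 0.22 higher, and ANCR siRNA replicate 2 lay 0.41 above the mean of the other 3 arrays.

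The first pattern is that other probe sets of a gene were called lower more often than its brightest one: among 6008 genes with several bright probe sets, 69 of the brightest and 275 of the 10037 others were lower, and 129 and 141 were higher. Loss of signal toward the 5' end is consistent with this, since where the brightest hardly moved a share of 0.735 of the deviating others lagged (341 against 123, 95% interval 0.692 to 0.775), and the lag correlated across probe sets with that between the control arrays (r = 0.23, 0.20 to 0.26). Of the 241 genes higher by at least 2-fold, 44 had other probe sets above the median level of the control arrays. In 43 of these 44 they were higher too. Their median log2 change was 0.79 (0.51 to 1.01), against 1.44 for the brightest. For these 44 genes the values argue against such a loss of signal as the whole source of the rise. Without a limit on level, the median was 0.45 (0.35 to 0.64) in 107 genes, with 97 higher. That value was too small for the rule of the test to decide. For the genes lower by at least 2-fold the test cannot decide. Their other probe sets above the median level of the control arrays were lower in 11 of 11 genes, with a median of -0.85 (interval -1.06 to -0.29). Loss of signal toward the 5' end would lower them, and so would a fall of the transcripts. The positions of probe sets along transcripts were not used here, so that the lagging ones lie nearer the 5' end is an assumption, and whether RNA handling or the state of the cells lay behind the lag was not tested.

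The second pattern is that the targeted RNA was not lower under its label. The 95% interval of 0.02 to 0.49 holds no loss at this probe set, which restates the reading and is no separate test of the knockdown. An exchange of one control array with one ANCR siRNA array is argued against by correlations within a label of at least 0.996, above the highest between labels, 0.992. An exchange of both groups as a whole cannot be told apart from correct labels by this RNA, since it gives a log2 change of -0.26, a loss smaller than 2-fold. The sequence of the siRNA was not used here, so cross-hybridization, loss in another part of the RNA and effects of the siRNA on other transcripts were not tested.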

How the results depend on the processing

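Under cyclic loess the targeted RNA and all 269 genes past 2-fold had the same direction. The block, the trend and the filter leave log2 changes as they are, and leaving out 1 array cannot turn a gene whose groups do not overlap, so those settings do not test direction. Tests of gene lists gave the same direction and side of the threshold in 150 cases. The call was lost in 20 and gained in 1, and the direction reversed in 5. The 150 include 16 tests under the intensity trend, which camera does not use, so those repeat the main tests. For log2 changes of named genes the numbers were 633 the same, 72 lost, 30 gained and 0 reversed. Same-numbered deviations correlated at 0.18, and with only 2 pairs a pairing is neither shown nor excluded. With the replicate block 166 probe sets were higher and 17 lower, and 128 genes were higher and 9 lower by at least 2-fold. That fit leaves fewer residual degrees of freedom, and it changed no call of a gene list. With dim probe sets left out 912 probe sets were higher and 925 lower, with fewer tested; at an adjusted threshold of 0.10, 1176 were higher and 1116 lower. The mean of a gene's probe sets gave 10 genes lower by at least 2-fold, and turned the p53 targets down and the endothelial and leukocyte markers up (adjusted p 0.930 for either), as fry did for the latter (0.914); the cause was not tested. The count of genes with 2 bright probe sets that agree, chosen after seeing the data, gave 44 higher and 6 lower, with fewer genes able to pass. With an estimated correlation the camera adjusted p was 0.219 for epidermal differentiation and for barrier lipids. It was 0.359 for differentiation factors, 0.350 for S phase and 0.529 for G2 and mitosis. No list passed in that test, whose few residual degrees of freedom leave it little power. Several lists also had estimated correlations above the preset, which weigh on the same calls. With fry S phase gave 0.0743 and G2 and mitosis 0.386. Cyclic loess gave 0.113 for G2 and mitosis; the cause was not tested. Leaving out each array in turn, with the lone array assumed to vary like the other group, gave 74 to 219 probe sets higher, 2 to 64 lower, 60 to 158 genes higher and 2 to 18 lower by at least 2-fold, with fewer samples. Each of the 4 arrays moved each count by over 1.5 times, and the lowest came without ANCR siRNA replicate 2. In the same fits the adjusted p ran from 9.78e-04 to 0.468 for G2 and mitosis, from 0.0571 to 0.913 for interferon response and from 0.640 to 0.913 for p53 targets. Interferon response turned down without control siRNA replicate 2 (0.378), and p53 targets without ANCR siRNA replicate 2 (0.913). RMA values give no signal over background, so which dim genes were expressed is not known.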

Other observations

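The families, the runs of neighbouring genes, the genes named here and the tests of fibroblast markers were chosen only after the result was seen. The tests of the contractile and mucosal lists were chosen before theirs.

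Several families, picked because members were seen among the largest rises, had further members higher, on arrays whose actin 3' minus 5' difference was 1.79 larger. Among genes higher by at least 2-fold were 6 of 15 kallikrein-related peptidases (Fisher's exact test, adjusted p = 9.13e-08 over 13 families). Some members of this protease family shed cornified cells. Protease inhibitors rose too, with 5 of 11 serpins of clade B (2.92e-07) and 4 of 15 whey acidic protein inhibitors (4.91e-05), among them SLPI, from 9.30 to 13.15. Of 11 SPRR and LCE proteins 7 were higher (1.51e-10), of 20 S100 proteins 6 (2.92e-07), of 44 keratins 8 (2.28e-07, with KRT8 lower at -0.75 in log2), of 11 interleukin-1 family members 4 (1.44e-05), of 11 desmosomal cadherins and plakophilins 2 (0.0109) and of 20 claudins 2 (0.0316, with CLDN11 lower at -1.58). Aldo-keto and retinol dehydrogenases, which act on retinoids and other carbonyls, had 4 of 25 higher (3.62e-04), among them AKR1C3 with a log2 change of 3.17. In contrast 1 of 43 collagens was higher (0.485), and COL8A1 (-1.56) and COL9A2 (-0.87) were lower. No integrin of 29 and no ribosomal protein of 57 passed with limma, with 3 higher and 2 lower, and 0 higher and 1 lower, at an unadjusted p under 0.05. All genes past 2-fold also passed after cyclic loess, but against 241 higher genes there were 97 without ANCR siRNA replicate 1, 60 without replicate 2, and 158 and 150 without control siRNA replicate 1 and 2. Genes within a family can share probes and regulation, so with families picked from the same genes these p-values are descriptive.

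Some of the genes that rose lay in clusters. In 1 run of 20 measured neighbours on chromosome 1, from IVL to S100A7, 14 were higher by at least 2-fold, against 241 of 19683 ordered genes overall. The highest count in any run was 6 in 10000 permutations of gene positions, which gives p = 0.0001, the smallest these can give. A run on chromosome 19 from KLK1 to VSIG10L held 7 of 20 (permutation p = 0.0001), and one on chromosome 1 from CGN to LCE3D held 5 of 20 (permutation p = 0.0154). The next runs held 4 of 20 (permutation p = 0.274), so most of the 241 lay outside these 3 runs. Paralogs lie side by side in these runs and can share probes.

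The 44.7-fold rise of KRT4 and the rise of KRT13 (log2 3.79), the keratin pair of internal stratified epithelia, on arrays with the 1.79 larger actin 3' minus 5' difference, led to the hypothesis of a joint rise of genes of non-cornified mucosal epithelium. A list of 21 such genes without that pair had a median log2 change of 0.23 and ranked above the other genes. The unadjusted camera p was 4.73e-09, and 0.0234 with an estimated correlation. On that unadjusted scale the estimated correlation gave 0.0274 for epidermal differentiation and 0.0174 for barrier lipids. The mucosal list therefore does not stand apart from them. Of the 21 genes, 7 were higher and none lower with limma, and 10 were higher and none lower at an unadjusted p under 0.05. CLCA4 rose 6.15-fold, CEACAM6 3.65-fold and MUC15 3.44-fold, while PSCA and CEACAM5 both differed by less than 0.01. This is consistent with such a rise, but SCEL and ECM1, which are also expressed in cornifying epidermis, are on the list, so a rise shared with epidermal differentiation stays open.

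The fall of VIM, POSTN and ACTA2 could come from fewer fibroblasts in the cultures labelled ANCR siRNA. As the source of the fall of VIM the tables argue against this: on the control arrays VIM read 13.14, while 7 matrix genes of the fibroblast list, transcripts abundant in fibroblasts, read 3.30 to 7.83, with a median difference from VIM of -7.69 in log2 (95% interval -8.95 to -7.10). For POSTN and ACTA2, with control levels of 7.90 and 7.94, fewer fibroblasts cannot be told apart from changes within the keratinocytes. The 9 markers above the median probe set of 5.67 had a median log2 change of -0.14 with an interval of -1.78 to 1.02, too wide to decide. Of these, S100A4, THY1, COL5A1 and FAP (4) were higher, and VIM and POSTN (2) were lower. Fewer fibroblasts alone would not give the 4 rises. A joint fall of contractile and matrix genes cannot be told apart from single changes, since a list of 23 such genes had a median of -0.16 (camera p = 0.0748, and 0.188 with an estimated correlation), with 3 higher and 7 lower at an unadjusted p under 0.05, and TGFBI (3.40-fold higher) and FN1 (1.75-fold lower) past the adjusted threshold. Loss of signal toward the 5' end also stays open for the lower genes. Their other probe sets had a median of -0.85 (interval -1.06 to -0.29), which such a loss and a fall of the transcripts could each give.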
